A study of Homo sapiens with 44 samples.

How the data were processed

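The samples were 44 libraries from IMR5/75, a human neuroblastoma line with amplified MYCN, carrying a short hairpin RNA (shRNA) against MYCN that tetracycline switches on. Cells were held at the G1/S boundary with thymidine for 18 h and collected at 0, 3, 6, 8, 10, 12, 14, 16, 18, 20 and 22 h after the block was washed out, with tetracycline (Tet plus, shRNA induced) or without it (Tet minus). Each of the 22 combinations of arm and time had 2 libraries, described in the series' design as biological replicates. Per the labels' protocols, total RNA received ERCC mix 1 spike-in transcripts, was depleted of ribosomal RNA and was made into directional libraries. The protocols do not give the basis of the spike-in amount relative to RNA mass.

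The deposited table holds whole-number read counts per gene, not normalised. Per the submitters' processing notes, the authors used TopHat2 2.0.5, HTSeq and the hg19 build; the HTSeq version, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads from a gene and its antisense or overlapping partner may therefore share counts, which concerns MYCN with MYCNOS and small nucleolar RNAs with the introns that hold them. The table has 23367 gene rows, of which 3929 had 0 counts in every library, and 92 ERCC rows, which were kept out of library sizes and gene tests. Multigene families such as the histones and ribosomal proteins share sequence, and their single-gene values are uncertain to that extent. No coordinates are given, since the annotation at hand was for another build; it was used only to find which genes contain small nucleolar RNAs.

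Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, glmQLFit and glmQLFTest) in 1 model with a mean for each of the 22 groups, so that all groups shared an estimate of spread with 22 residual degrees of freedom. The filter left 14534 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. Standard errors (SE) are log2 fold change divided by the square root of the F statistic. Library-scaled counts (CPM in edgeR) use the TMM library sizes, and log2 CPM values a prior count of 2. The comparisons were Tet plus minus Tet minus, averaged over the 7 times from 0 to 14 h, over the 4 times from 16 to 22 h and at each time, the difference between those averages, the change over time in each arm, and the dependence of the arm difference on time from 0 to 14 h. At 0 to 14 h, libraries of both arms with the same replicate number share a lane number. At 16 to 22 h the Tet plus libraries carry another form of title and other lane numbers than the Tet minus libraries, read here as another sequencing run, so arm and run are confounded there. Lane numbers also change along the course, so changes over time were compared within lane sets as well (6 against 0 h, 12 against 8 h, 22 against 16 h).

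The 27 gene lists were written from general knowledge and tested with limma 3.58.1 camera (preset correlation 0.01), and again with an estimated correlation and with fry. Named genes were MYCN and the MYC network, the 15 highest and 15 lowest log2 fold changes at 0 to 14 h and the 5 highest and 5 lowest at 16 to 22 h among genes past the threshold with a mean log2 CPM of at least 3 and the same sign at each time, up to 4 members of each list by adjusted p, the 10 widest ranges over time in Tet minus cells and the 10 smallest interaction p-values. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined, apart from those marked in the text as chosen later. The ERCC share of counts was compared by a 2-sided exact permutation test within time points.

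Replicate numbers were checked for pairing. At 0 to 14 h, the deviations from group means of same-numbered libraries of the 2 arms correlated at each of the 7 times across 10090 genes (lowest r 0.373, median 0.781). At 16 to 22 h they correlated at each of the 4 times (lowest r 0.263). The numbers were therefore taken to pair the arms, and a fit with replicate number as a block is given beside an arm comparison where it moves a count by more than 1.5-fold. Within an arm, same-numbered libraries also shared deviations across most pairs of times (median r 0.592 in Tet minus and 0.564 in Tet plus). The main p-values for averages over times and for courses take libraries of different times as independent, which these values argue against. Replicate pairs differed by more than counting noise (chi-square per gene 8.90 to 51.3), so no library was counted as a duplicate.

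The steps were tested on simulated counts for 14534 genes, with 67, 67 and 66 genes changed 1.25-fold, 1.5-fold and 2-fold in each comparison. The simulated libraries were drawn independently, without deviations shared by replicate number or lane. Recovery and false calls in the data may therefore differ from those given here. In the simulated 0 to 14 h arm comparison, 34.3% of genes changed 1.25-fold, 70.1% of those changed 1.5-fold and 93.9% of those changed 2-fold were recovered, with 7 false calls. For the simulated comparison at 6 h alone these shares were 1.49%, 11.9% and 60.6%, with 3 false calls. For the simulated dependence on time from 0 to 14 h they were 0%, 0% and 47.0%, with 6 false calls. Alternatives were DESeq2 1.42.0, its size factors with the edgeR test, scaling to the ERCC rows, no filter or a stricter filter on low counts (10 CPM in 2 libraries), the replicate block, subsets of libraries and times, and leaving out each library in turn. Groups of 2 libraries are too small for an outlier test, and none was made.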

Results

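Transcripts were counted in 44 libraries from IMR5/75 neuroblastoma cells followed through a cell cycle after release from a thymidine block, with MYCN left high (Tet minus, 22 libraries) or with a MYCN shRNA induced (Tet plus, 22 libraries). The question was how lowering MYCN changes gene expression along the cycle. No library had tetracycline without this shRNA or with a control hairpin. Effects of the drug, or of the hairpin on other transcripts, therefore cannot be told apart from those of lowered MYCN. Assigned gene counts ranged from 10.9 to 25.3 M (mega) per library (median 20.1 M), and 15605 to 16398 genes were detected per library. The 8 Tet plus libraries at 16 to 22 h had 10.9 to 19.8 M counts. In these 8 libraries ERCC transcripts made up 0.0543% to 0.376% of counts, against 1.13% to 3.43% in the Tet minus libraries at 16 to 22 h. At 0 to 14 h they made up 0.736% to 5.85% in the Tet plus and 0.806% to 4.25% in the Tet minus libraries. Small nucleolar and Cajal body RNAs took 0.935% to 2.41% of gene counts in the 8 libraries, against 0.289% to 0.713% (median 0.546%) in Tet minus at 16 to 22 h. At 0 to 14 h they took 0.294% to 0.806% (median 0.476%) in Tet plus and 0.224% to 0.63% (median 0.446%) in Tet minus libraries. At 0 to 14 h the ERCC share did not differ detectably between arms (mean log2 difference -0.00601, 2-sided exact permutation p = 0.982, higher in Tet plus at 4 of 7 times).

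**Figure D1:**
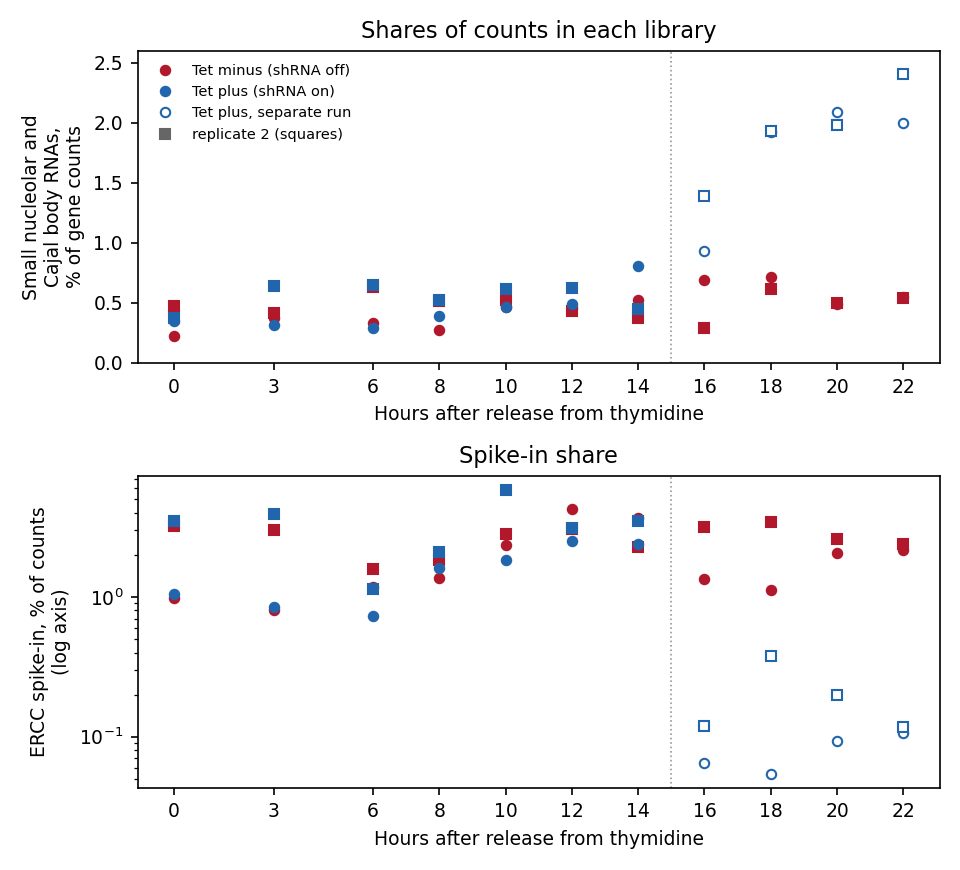
Share of gene counts taken by small nucleolar and Cajal body RNAs (percent, upper panel) and share of counts taken by ERCC spike-in (percent, log axis, lower panel) in each of the 44 libraries against hours after release. Each point is 1 library (squares are replicate 2), and the 8 Tet plus libraries at 16 to 22 h (open symbols, separate run, right of the dotted line) hold 0.935% to 2.41% of these RNAs and 0.0543% to 0.376% ERCC.

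MYCN, the targeted transcript, was lower in Tet plus cells by 17.3% at 0 to 14 h (log2 fold change -0.27, SE 0.0460, adjusted p = 2.71e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for genes throughout). It averaged 1036 ± 86.7 CPM in Tet plus and 1257 ± 142 CPM in Tet minus libraries (SD, n = 14 per arm), and its mean was lower at 7 of 7 times. Both Tet plus libraries lay below both Tet minus libraries at 6 of these 7 times, the exception being 0 h (log2 fold change -0.08, adjusted p = 0.858). At 16 to 22 h MYCN was 16.5% lower (log2 fold change -0.26, SE 0.0608, adjusted p = 0.000787). It averaged 1019 ± 109 against 1222 ± 146 CPM (SD, n = 8 per arm). The SDs for 0 to 14 h and 16 to 22 h span 7 and 4 times with 2 libraries each. They mix change over time with replicate spread, and libraries of different times are not independent replicates. Taken singly, the difference passed the threshold at 12 h (log2 fold change -0.45, adjusted p = 0.0343) and 16 h (log2 fold change -0.58, adjusted p = 0.000826). The block added 6 h (adjusted p = 0.0208) and 10 h (adjusted p = 0.0198). At 22 h the log2 fold change was -0.03 (adjusted p = 0.889), and the libraries of the arms overlapped. With ERCC scaling the MYCN difference was -0.15 at 0 to 14 h (adjusted p = 1) and 4.12 at 16 to 22 h, where all genes shifted. Among its partners and antagonists, MXD4 and MXD1, which compete with MYC proteins for MAX, rose at 0 to 14 h by 0.98 (SE 0.0692) and 0.61 (SE 0.0636) on the log2 scale. Of the 13 measured members of the MYC network, 3 rose and 3 fell, counts that were the same adjusted over the list alone; the median log2 fold change was -0.09 and the mean 0.12, and the set test (camera) did not pass (adjusted p = 0.381). The 3 that fell were MYCN, MAX (-0.15, SE 0.0515, adjusted p = 0.0244) and MGA (-0.19, SE 0.0720, adjusted p = 0.0313). The MAX call ended without any of 6 of the 28 libraries (adjusted p up to 0.0658, without Tet minus 0 h replicate 1) and the MGA call without any of 14 (up to 0.0956, without Tet minus 8 h replicate 2). Both ended without Tet minus 6 h replicate 2 (0.0567 and 0.0938), and 1 member fell when the 28 libraries were fitted alone. At 16 to 22 h 4 rose and 2 fell (3 and 2 adjusted over the list alone, set adjusted p = 0.177).

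**Figure D2:**
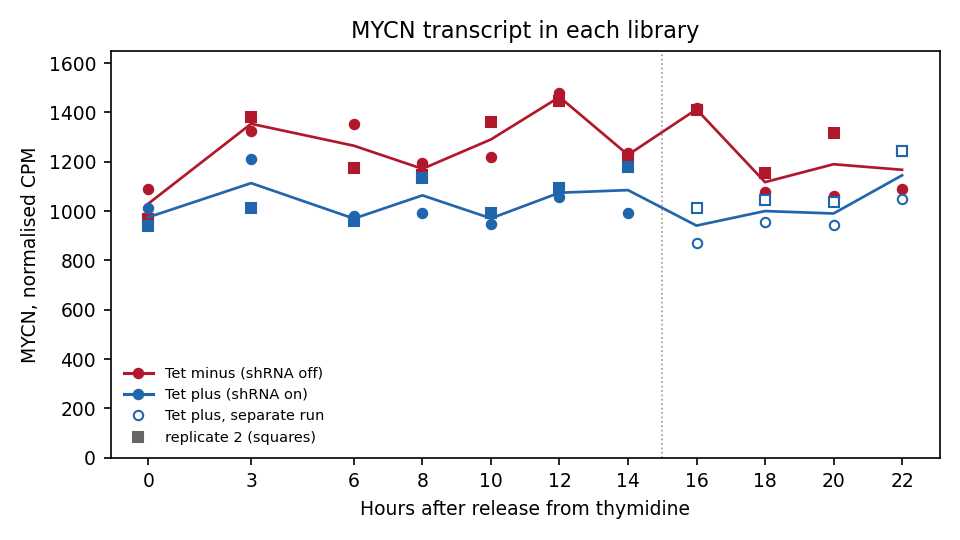
MYCN level (normalised CPM) in each library against hours after release; lines join the means of the 2 libraries per group, and squares are replicate 2. The group mean is lower in Tet plus at 7 of 7 times up to 14 h and at 4 of 4 later times. At 0 h (975.2 against 1030 CPM) and 22 h (1145 against 1168 CPM) the means lie close and libraries of the arms overlap.

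Of the lists tested at 0 to 14 h, the smallest set p-value belonged to genes of ribosome assembly, which were lower with the shRNA. Of 50 ribosome biogenesis genes, 49 fell and 0 rose (50 fell adjusted over the list alone), with a median log2 fold change of -0.59. RRP12, needed for export of ribosomal subunits, fell by 0.90 (SE 0.0470, adjusted p = 8.69e-14). MYBBP1A, a nucleolar MYB-binding protein, fell by 0.92 (SE 0.0489, adjusted p = 9.75e-14), and RRS1, a ribosome assembly factor, fell by 1.01 (SE 0.0608, adjusted p = 1.10e-12). The set test gave an adjusted p = 5.17e-58, which held with an estimated correlation (adjusted p = 0.000116). Nucleotide synthesis genes also fell, 26 of 29 (28 adjusted over the list alone; median -0.39, set adjusted p = 2.05e-15, and adjusted p = 0.0347 with an estimated correlation). They included PFAS, a purine synthesis enzyme (log2 fold change -0.56, SE 0.0480), and IMPDH1, which makes the guanine nucleotide precursor (-0.68, SE 0.0612).

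Other growth and metabolic groups moved down as well, with smaller changes. Mitochondrial ribosomal proteins fell in 31 of 36 (34 adjusted over the list alone; median -0.29, set adjusted p = 2.23e-12, and adjusted p = 0.0813 with an estimated correlation). MRPS12 was among them (log2 fold change -0.76, SE 0.0660). Translation factors and aminoacyl-tRNA synthetases fell in 23 of 31 (24 adjusted over the list alone; median -0.23, set adjusted p = 5.17e-06, and adjusted p = 0.196 with an estimated correlation), for example the initiation factor subunit EIF3B (-0.39, SE 0.0534). Cytosolic ribosomal proteins fell in 14 of 51 (13 adjusted over the list alone, median -0.12). Over all genes 3095 of 14534 fell, so the share in this list was near that of all genes. Its set test gave an adjusted p = 0.00488, and adjusted p = 0.617 with an estimated correlation. Chaperonins and chaperones fell in 16 of 18 (17 adjusted over the list alone; median -0.29, set adjusted p = 6.65e-09, and adjusted p = 0.0813 with an estimated correlation). The mitochondrial chaperones TRAP1 (-0.55, SE 0.0427) and HSPD1 (-0.52, SE 0.0659) were among them. Glycolysis genes fell in 13 of 18 and rose in 1 (the same adjusted over the list alone; median -0.27, set adjusted p = 1.36e-06, and adjusted p = 0.0813 with an estimated correlation). LDHA, which converts pyruvate to lactate, fell by 0.87 (SE 0.0580). The 1 rise ended without any of 16 of the 28 libraries and when the 28 were fitted alone. Cholesterol synthesis genes fell in 13 of 20 (14 down and 1 up adjusted over the list alone; median -0.21, set adjusted p = 0.00119, and adjusted p = 0.201 with an estimated correlation). In this list 1 gene rose with the replicate block, and 1 without any of 7 libraries.

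Polyamine synthesis genes were split. ODC1, the first enzyme of the pathway, fell by 0.79 (SE 0.0688, adjusted p = 9.59e-10) and AMD1, which supplies aminopropyl groups, by 0.58 (SE 0.0698), while PAOX, a polyamine oxidase, rose by 0.87 (SE 0.0955). In all 5 of 10 fell and 2 rose (6 and 2 adjusted over the list alone), but 1 rose without any of 7 of the 28 libraries. The set test did not pass (adjusted p = 0.0609). It passed with the block (adjusted p = 0.00611) and with fry, which does not compare the set with other genes (adjusted p = 5.49e-06). Among ATF4 targets and amino acid response genes 9 of 20 fell and 4 rose (the same adjusted over the list alone, set adjusted p = 0.0915); the amino acid transporter SLC7A5 fell by 0.94 (SE 0.0763), and the lipoprotein receptor VLDLR rose by 0.54 (SE 0.0666).

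Several p53 targets and noradrenergic genes rose at 0 to 14 h. Of 18 measured p53 targets, 8 rose and 0 fell (the same adjusted over the list alone; median 0.20, set adjusted p = 5.00e-05, and adjusted p = 0.182 with an estimated correlation). With the replicate block 13 rose. TP53INP1, a stress-response gene, had the largest increase among genes meeting the naming rule (1.40, SE 0.0938, adjusted p = 7.24e-12), and CDKN1A, encoding the kinase inhibitor p21, rose by 0.71 (SE 0.0681). Among G1 cyclins and CDK inhibitors, 7 of 20 rose and 8 fell (7 and 9 adjusted over the list alone, set adjusted p = 0.395). The kinase inhibitor CDKN1C rose by 1.14 (SE 0.150), while CDK4, the G1 kinase, fell by 0.73 (SE 0.0478) and its partner CCND3 by 0.58 (SE 0.0618). Noradrenergic identity genes rose in 11 of 19 (12 adjusted over the list alone; median 0.34, set adjusted p = 1.98e-05, and adjusted p = 0.122 with an estimated correlation). From the 28 libraries alone 10 rose and 1 fell. SLC6A2, the noradrenaline transporter, rose by 1.01 (SE 0.0651), and DDC, an enzyme of catecholamine synthesis, by 0.97 (SE 0.0734). Neuronal differentiation genes rose in 14 of 33 and fell in 3 (the same adjusted over the list alone; median 0.33, set adjusted p = 0.00624, and adjusted p = 0.555 with an estimated correlation). With the block 21 rose and 5 fell, and without Tet plus 14 h replicate 1 9 rose. The microtubule regulator STMN4 was higher by 1.06 (SE 0.0827) and the adhesion molecule CNTN1 by 0.65 (SE 0.0580). Interferon response genes rose in 9 of 17 and fell in 1 (12 and 1 adjusted over the list alone; median 0.32, set adjusted p = 0.00307, and adjusted p = 0.0813 with an estimated correlation). They included STAT2 (0.42, SE 0.0363), a subunit of the interferon-activated transcription factor. With the block 13 interferon genes rose and 2 fell.

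Several lists did not pass the set test at 0 to 14 h. In the BCL2 family 5 of 13 rose and 1 fell (the same adjusted over the list alone, set adjusted p = 0.395): BBC3, which promotes apoptosis, rose by 0.97 (SE 0.187), BCL2, which restrains it, rose by 0.43 (SE 0.0862), and BID fell by 0.45 (SE 0.0475). In this family 3 rose without Tet minus 3 h replicate 1, Tet minus 10 h replicate 1 or Tet plus 0 h replicate 2. In it 2 fell with the block, and 2 without Tet plus 0 h replicate 1, Tet minus 0 h replicate 2 or Tet minus 14 h replicate 2. Immediate early genes rose in 1 of 19 and fell in 4 (the same adjusted over the list alone, set adjusted p = 0.423), and 7 fell with the block or without Tet plus 12 h replicate 1. The mesenchymal and Schwann-like list rose in 3 of 17 and fell in 1 (2 and 1 adjusted over the list alone, set adjusted p = 0.452), and with the block 8 rose and 4 fell. Among those that rose, the matrix genes FN1 (0.58, SE 0.230, adjusted p = 0.0464) and COL1A1 (0.42, SE 0.147, adjusted p = 0.0229) lost their calls without any of 14 and any of 5 libraries. Without Tet plus 0 h replicate 2 both calls ended (adjusted p = 0.131 and 0.0557) and 1 of the list rose. MHC class I and antigen presentation genes rose in 1 of 7 (1 adjusted over the list alone, set adjusted p = 0.663), and with the block 2 rose and 1 fell. The 1 was TAPBP (0.25, SE 0.0839, adjusted p = 0.0187), whose call ended without Tet plus 3 h replicate 1 (adjusted p = 0.054) or Tet plus 14 h replicate 1 (0.0506), and 1 of these genes fell without any of 6 libraries. Abundant non-coding RNAs fell in 1 of 8 (1 adjusted over the list alone, set adjusted p = 0.281), the small nucleolar RNA host SNHG1 (log2 fold change -0.59, SE 0.0536). With the block 1 of them rose and 2 fell; 1 rose without any of 4 libraries and 2 fell without Tet plus 3 h replicate 2 or Tet plus 8 h replicate 2. Of 12 epithelial markers 2 were measured and 1 rose, also adjusted over the list alone. None of the 13 mitochondrially encoded mRNAs was in the table. Genes near MYCN on the chromosome rose in 2 of 9 and fell in 2 (the same adjusted over the list alone, set adjusted p = 0.822). With the block 4 rose, from the 28 libraries alone 1 rose and 1 fell, and without 1 library 1 to 4 rose and 1 to 2 fell. DDX1, co-amplified with MYCN in many neuroblastomas, had a log2 fold change of -0.10 (SE 0.0394, adjusted p = 0.0435; 0.015 with ERCC scaling) and NBAS one of 0.17 (SE 0.0664, adjusted p = 0.0424). Leaving out any of 19 of the 28 libraries ended the DDX1 call (adjusted p up to 0.095, without Tet minus 12 h replicate 2), and any of 14 ended the NBAS call (up to 0.104, without Tet plus 8 h replicate 2).

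**Figure D3:**
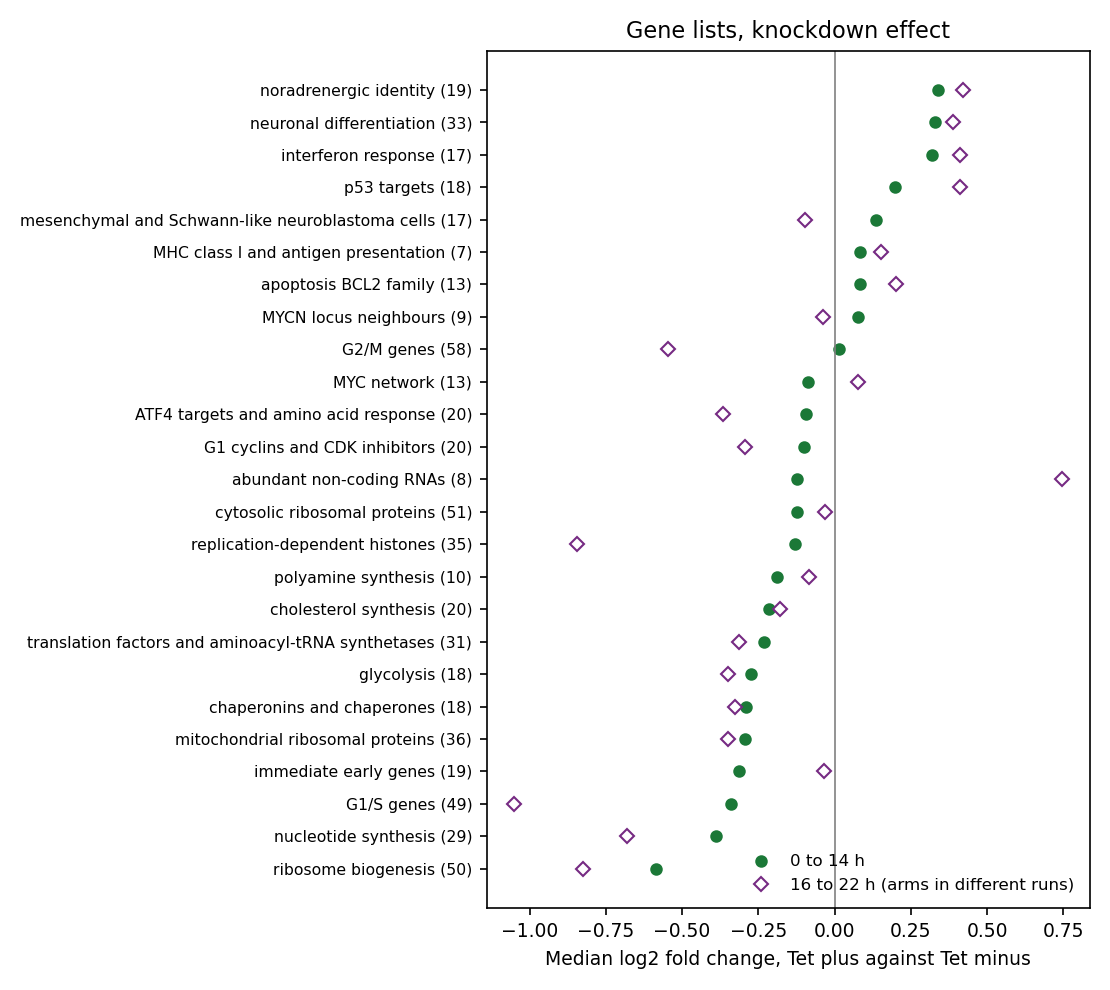
Median log2 fold change (Tet plus against Tet minus) over the measured members of each gene list at 0 to 14 h (filled circles) and at 16 to 22 h (open diamonds, arms in different runs); numbers of measured genes are in parentheses. Ribosome biogenesis lies at -0.59 and -0.83, and G1/S genes move from -0.34 to -1.05.

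Over all genes, 6019 of 14534 differed between arms at 0 to 14 h (2924 higher and 3095 lower in Tet plus), and of these 166 were at least 2-fold higher and 45 at least 2-fold lower. Other genes with large increases by the naming rule were OPTN, an autophagy receptor (1.40, SE 0.0996), GCHFR, a regulator of tetrahydrobiopterin synthesis (1.17, SE 0.0877), the cyclin CCNG2 (1.15, SE 0.0642), and CADPS, which primes dense-core vesicles for release (1.13, SE 0.0573). DBH, the last enzyme of noradrenaline synthesis, was higher by 1.19 (SE 0.428, adjusted p = 0.0265), a call that ended without any of 11 of the 28 libraries (adjusted p up to 0.0827, without Tet plus 8 h replicate 1). Among the 3561 genes meeting the naming rule, the largest decreases included SLC38A5, an amino acid transporter (-1.42, SE 0.0956), DDN, which encodes dendrin (-1.21, SE 0.0768), the organic anion transporter SLCO4A1 (-1.17, SE 0.0693), NAGPA, an enzyme of lysosomal targeting (-1.14, SE 0.0699), and MCM3, a subunit of the replicative helicase (-1.13, SE 0.0529). Lower too were DHX37, a helicase of ribosome assembly (-1.04, SE 0.0437), and CD3EAP, an RNA polymerase I subunit (-1.03, SE 0.0585). These changes are relative to the bulk of genes: scaling to the ERCC rows moved the median of all genes from 0.01 to 0.13 and left 48 genes past the threshold (44 higher, 4 lower).

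Taken time by time, 228, 395, 1031, 499, 494, 609 and 781 genes differed between arms at 0, 3, 6, 8, 10, 12 and 14 h. With the replicate block the counts were 1174, 1301, 2525, 1800, 1504, 1846 and 2353. These single-time counts rested on few libraries. Without 1 of the 4 libraries of a time they dropped as low as 33, 25, 91, 92, 151, 120 and 173, the lowest at 3 h without Tet plus 3 h replicate 2. Ribosome biogenesis genes were lower at each of these times, with between 21 and 31 of 50 past the threshold, 34 to 41 with the block and 3 to 27 without 1 library. The 3 came at 0 h without Tet minus 0 h replicate 2. At 0 h the median of this list was -0.55, while the MYCN transcript differed by -0.08 (adjusted p = 0.858). G1/S genes, which serve DNA replication, were little separated early (1 of 49 lower at 0 h, median -0.22, set adjusted p = 1.79e-06, and adjusted p = 0.517 with an estimated correlation) and well separated at 14 h (37 of 49 lower, median -0.84, set adjusted p = 4.74e-64, and adjusted p = 0.000232 with an estimated correlation). With the block 3 were lower at 0 h. At 14 h 18 to 40 were lower without 1 library, the fewest without Tet plus 14 h replicate 1. Over 0 to 14 h as a whole, 41 of 49 G1/S genes fell (45 adjusted over the list alone; median -0.34, set adjusted p = 8.79e-19, and adjusted p = 0.0813 with an estimated correlation). ORC1, which marks replication origins, fell by 0.63 (SE 0.0564), and MCM10, an origin-firing factor, by 0.55 (SE 0.0510). G2/M genes rose in 10 of 58 and fell in 7 (6 and 7 adjusted over the list alone, set adjusted p = 0.686). Any of 9 libraries moved their number that rose over 1.5-fold, down to 3 without Tet plus 6 h replicate 1 or Tet plus 14 h replicate 1. Replication-dependent histones fell in 8 of 35 (5 adjusted over the list alone, set adjusted p = 0.0915). Any of 7 libraries moved this number, to 13 without Tet plus 6 h replicate 1 and to 5 without each of the other 6, and 1 rose without Tet minus 3 h replicate 1.

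**Figure D4:**
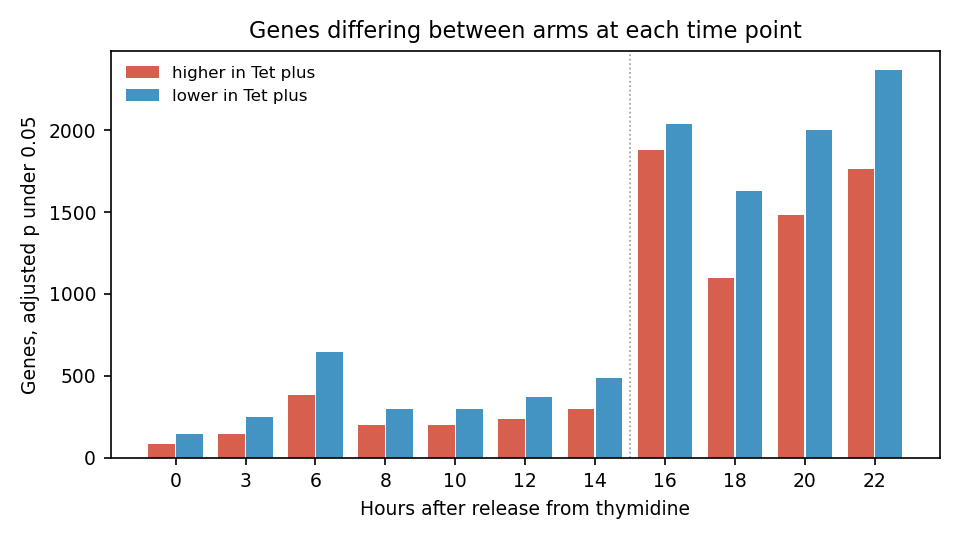
Number of genes higher (red) or lower (blue) in Tet plus than in Tet minus cells at each time after release (adjusted p under 0.05, 2 libraries per group, 14534 genes tested). Counts lie between 228 and 1031 in all up to 14 h and between 2721 and 4127 at 16 to 22 h, where the arms come from different runs.

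Without the shRNA, histone genes peaked before mitotic genes after release. Histone genes, transcribed during DNA synthesis, were highest at 3 h: 30 of 35 were higher at 3 h than at 0 h in Tet minus cells (median 2.23 log2, set adjusted p = 1.76e-194, and adjusted p = 1.84e-07 with an estimated correlation). G2/M genes peaked at 8 h, when 48 of 58 were higher (median 1.28, set adjusted p = 2.50e-174, and adjusted p = 3.34e-08 with an estimated correlation). AURKA, a mitotic kinase, was 2.34 log2 above its 0 h level at 8 h (adjusted p = 5.34e-13 over the course). G1/S genes were lowest at 10 h, with 21 of 49 lower than at 0 h (median -0.49, set adjusted p = 1.39e-29, and adjusted p = 0.00607 with an estimated correlation), and were back at their starting level at 18 h (mean log2 CPM 7.36 ± 0.0502 against 7.31 ± 0.0291, SD, n = 2). CCNE2, a cyclin of S-phase entry, was down to -2.22 at 8 h (adjusted p = 1.73e-07 over the course). Histones were high again at 16 h (27 of 35, median 1.74) and G2/M genes at 22 h (34 of 58, median 0.70, set adjusted p = 3.25e-52, and adjusted p = 0.000331 with an estimated correlation).

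Over the whole Tet minus course 2869 of 14534 genes changed. The widest ranges included the histone genes HIST1H2AB (3.66 log2, adjusted p = 1.59e-11) and HIST3H2BB (3.33, adjusted p = 5.90e-08), and PIF1, a DNA helicase (3.40, adjusted p = 7.68e-07). The count fell to 1711 without Tet minus 3 h replicate 2 and to 1326 when the Tet minus libraries were fitted alone. Within lane sets, 341 genes differed between 6 and 0 h (270 higher, 71 lower), 121 between 12 and 8 h (10 higher, 111 lower) and 239 between 22 and 16 h (170 higher, 69 lower). With the replicate block these counts were 917, 280 and 1785, and 6805 genes changed over the course.

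With the shRNA induced, histone genes peaked at the same sampled time and G2/M genes at a later one. In Tet plus cells 29 of 35 histones were higher at 3 h than at 0 h (median 1.72, set adjusted p = 6.83e-290, and adjusted p = 4.01e-09 with an estimated correlation). G2/M genes were highest at 10 h (mean log2 CPM 7.91 ± 0.0395, against 7.73 ± 0.197 at 8 h), while in Tet minus cells they were highest at 8 h (7.96 ± 0.0428, against 7.73 ± 0.0196 at 10 h; SD, n = 2 each). The times of the peaks were not compared by a test. The G2/M list was lower in Tet plus than in Tet minus cells at 8 h (median -0.23, set adjusted p = 5.32e-08, and adjusted p = 0.106 with an estimated correlation). It was higher at 12 h (median 0.31, set adjusted p = 1.07e-11, and adjusted p = 0.0684 with an estimated correlation). The 8 h difference rested mainly on replicate 2: mean log2 CPM was 7.87 and 7.59 in Tet plus replicates 1 and 2, against 7.93 and 7.99 in Tet minus. In Tet plus replicate 1 the level at 10 h was 7.88, close to that at 8 h. G1/S genes stayed low: 34 of 49 were below their 0 h level at 14 h (median -0.79, set adjusted p = 9.32e-51, and adjusted p = 0.000880 with an estimated correlation). Over 0 to 22 h 5698 genes changed in Tet plus cells, and over 0 to 14 h, without the libraries of the other run, 1510. Within lane sets 364 genes differed between 6 and 0 h (258 higher, 106 lower), 32 between 12 and 8 h (5 higher, 27 lower) and 1052 between 22 and 16 h (376 higher, 676 lower). With the replicate block these counts were 1248, 118 and 2653, and 9241 genes changed over 0 to 22 h.

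A direct test of whether the arm difference depended on time between 0 and 14 h passed for 2 genes by edgeR. It passed for 22 with the replicate block and 33 by DESeq2. Without the block 265 of 14534 genes had an unadjusted p under 0.05, a smaller share than the 0.05 expected without any effect. The 265 are therefore no sign of further genes, and the test without the block gave fewer small p-values than chance would. Between 0 and 5 genes passed when 1 of the 28 libraries was left out, 0 when the 28 libraries at 0 to 14 h were fitted alone and 954 over all 11 times. The 2 genes of the main fit were ZNF367, a zinc finger gene (adjusted p = 0.0295), and the histone HIST1H3D (adjusted p = 0.0425). The arm difference of ZNF367 went from 0.08 at 0 h to -1.23 at 14 h. That of HIST1H3D went from -0.03 at 0 h through 0.61 at 8 h to -1.05 at 14 h. Leaving out 1 library ended the ZNF367 call for 15 of the 28 and the HIST1H3D call for 24 of the 28 (adjusted p up to 0.285 for each, without Tet plus 14 h replicate 1). AURKA did not pass (adjusted p = 0.128). It passed with the block (adjusted p = 0.0157), by DESeq2 (adjusted p = 7.53e-05) and over all 11 times (adjusted p = 2.98e-06). Its arm difference was -0.56 at 6 h and 0.49 at 12 h.

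**Figure D5:**
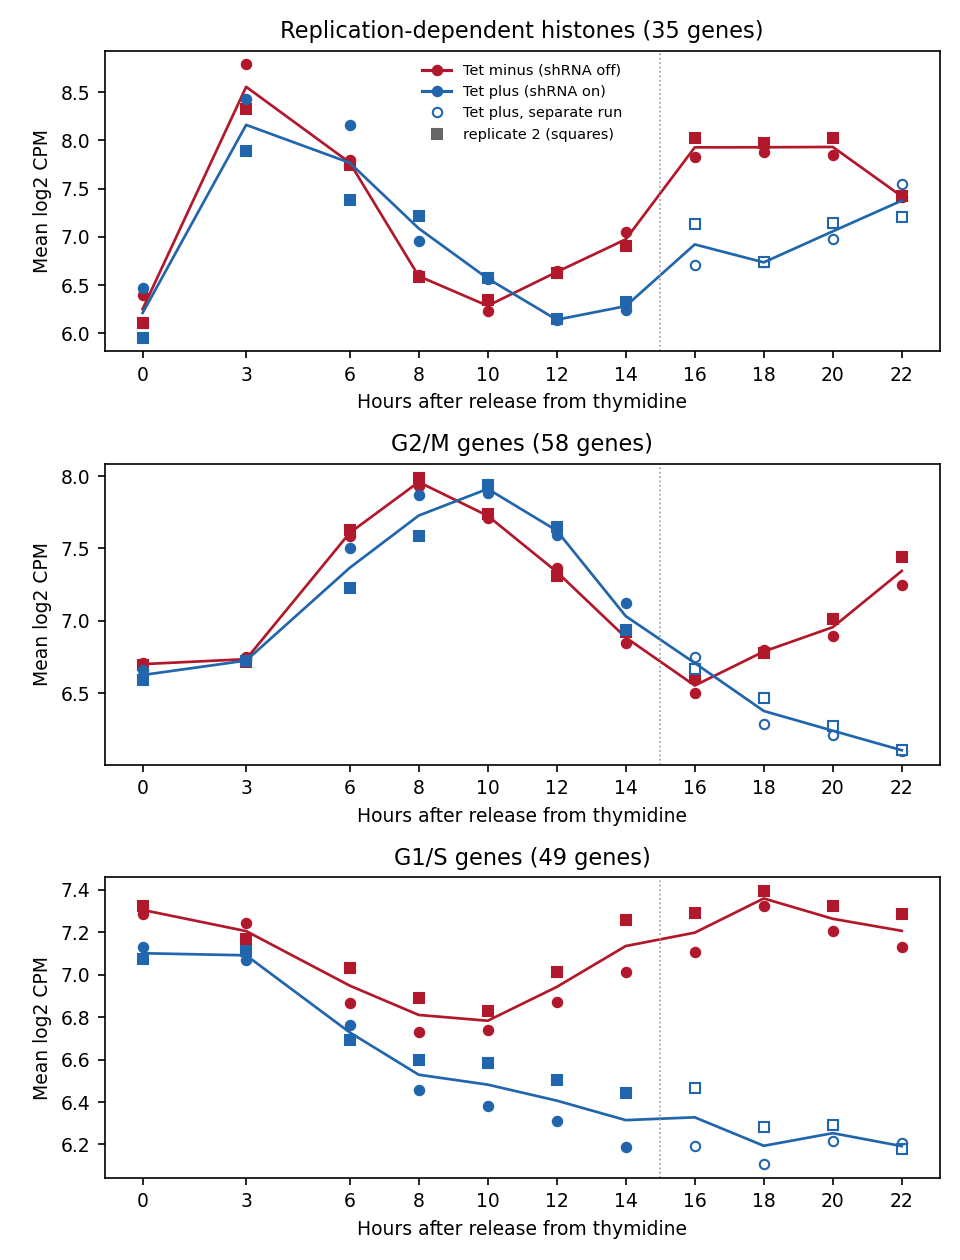
Mean log2 CPM over replication-dependent histones (35 genes), G2/M genes (58) and G1/S genes (49) in each library against hours after release; lines join means of 2 libraries, squares are replicate 2, and open symbols are Tet plus libraries of the separate run. G2/M genes peak at 8 h in Tet minus (7.96) and 10 h in Tet plus cells (7.91), and G1/S genes are at 7.14 and 6.32 at 14 h.

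Averaged over 16 to 22 h, replication and mitosis genes were lower in Tet plus cells, but not at every time. All 49 measured G1/S genes fell (49 adjusted over the list alone; median -1.05, set adjusted p = 2.55e-52, and adjusted p = 0.00283 with an estimated correlation). MCM3 fell by 2.03 (SE 0.0719, adjusted p = 1.27e-17), and TK1, the thymidine kinase of the salvage pathway, by 1.81 (SE 0.0884, adjusted p = 7.29e-15). G2/M genes fell in 48 of 58 (49 adjusted over the list alone; median -0.55, set adjusted p = 8.57e-18, and adjusted p = 0.0796 with an estimated correlation). Histones fell in 28 of 35 (31 adjusted over the list alone; median -0.85, set adjusted p = 4.12e-12, and adjusted p = 0.202 with an estimated correlation), HIST1H2BF by 2.00 (SE 0.169). Averaged over these times 1 histone rose without Tet minus 16 or 22 h replicate 2, and 1 G2/M gene rose from the 16 libraries alone. At 16 h alone the G2/M list was higher in Tet plus (11 rose and 3 fell, median 0.14, set adjusted p = 0.016, and adjusted p = 0.464 with an estimated correlation). Its medians were -0.38, -0.69 and -1.36 at 18, 20 and 22 h. The number of G2/M genes that rose at 16 h went down to 3 without Tet minus 16 h replicate 1, and the number that fell to 1 without Tet plus 16 h replicate 2. At 22 h 4 of 35 histones fell (median -0.04, set adjusted p = 0.63), 7 with the block and 0 without Tet plus 22 h replicate 2. Arm and sequencing run were confounded at these times, and with ERCC scaling, which moved the median of all genes from 0.02 to 4.40, 14510 genes were higher in Tet plus and 0 lower, so that the directions hold relative to the bulk of genes.

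At 16 to 22 h ribosome biogenesis genes were again lower, in 49 of 50 (49 adjusted over the list alone; median -0.83, set adjusted p = 5.75e-36, and adjusted p = 0.00283 with an estimated correlation), and nucleotide synthesis genes were so in 28 of 29 (28 adjusted over the list alone; median -0.68, set adjusted p = 2.42e-18, and adjusted p = 0.0114 with an estimated correlation). The nucleoside transporter SLC29A1 fell by 1.81 (SE 0.0848) and SLCO4A1 by 1.81 (SE 0.0978). Set tests also passed downward for mitochondrial ribosomal proteins (26 of 36 fell, 2 rose), translation factors and synthetases (21 of 31 fell), chaperones (12 of 18), glycolysis (13 of 18), ATF4 targets (9 of 20 fell, 2 rose) and G1 cyclins and CDK inhibitors (11 of 20 fell, 4 rose). In that order the adjusted p with an estimated correlation was 0.239, 0.234, 0.258, 0.202, 0.270 and 0.202, so none of these 6 calls held. Adjusted over the list alone, the numbers that fell were 26, 22, 12, 13, 9 and 11. The mitochondrial ribosomal protein genes that rose went from 2 to 1 without Tet minus 16, 18, 20 or 22 h replicate 1.

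Upward shifts at 16 to 22 h were seen for p53 targets (11 of 18 rose, 1 fell), noradrenergic genes (11 of 19 rose) and interferon response genes (10 of 17 rose); adjusted over the list alone 12, 12 and 10 rose and 1, 1 and 0 fell. Their set adjusted p-values were 0.00209, 0.000274 and 0.0257, and the adjusted p with an estimated correlation was 0.265, 0.202 and 0.202. The set test did not pass for neuronal differentiation (9 of 33 rose, 3 fell; adjusted p = 0.0639, and 0.00240 with the block) or cholesterol synthesis (9 of 20 fell, 2 rose; adjusted p = 0.0927, and 0.0355 with the block). It did not pass for cytosolic ribosomal proteins (12 of 51 fell), polyamine synthesis (3 of 10 rose, 4 fell), the BCL2 family (4 of 13 rose, 2 fell), immediate early genes (6 of 19 rose, 3 fell), the mesenchymal list (5 of 17 rose, 1 fell), MHC class I genes (2 of 7 rose, 1 fell), MYCN neighbours (3 of 9 rose, 3 fell) or abundant non-coding RNAs (6 of 8 rose, 1 fell). Adjusted over the list alone, these 10 lists had 8, 2, 0, 3, 4, 6, 5, 2, 3 and 6 genes higher and 3, 9, 10, 4, 2, 3, 1, 1, 3 and 1 lower. For immediate early genes, the mesenchymal list and MYCN neighbours the median was below 0 and the mean above it. Of the 2 epithelial markers 1 rose, also adjusted over the list alone.

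Several of these list counts at 16 to 22 h moved with the block. More genes rose for cytosolic ribosomal proteins (7 in place of 0), neuronal differentiation (22 in place of 9), the BCL2 family (8 in place of 4), the mesenchymal list (8 in place of 5) and glycolysis (1 in place of 0). More fell for the mesenchymal list (5 in place of 1), p53 targets (2 in place of 1) and noradrenergic and interferon response genes (1 in place of 0 in each). From the 16 libraries alone 7 of the BCL2 family and 2 cytosolic ribosomal protein genes rose, and 0 p53 targets and 0 MHC class I genes fell. Without 1 library the neuronal genes that rose went down to 5 (without Tet plus 16, 18 or 22 h replicate 1 or Tet minus 18 h replicate 2). Those of the mesenchymal list went down to 3 (without any Tet plus replicate 1 or Tet minus 18 or 20 h replicate 2), and 2 of it fell without Tet plus 16, 18 or 22 h replicate 2. Immediate early genes that rose went from 6 to 3 without Tet plus 22 h replicate 2. Those that fell went from 3 to 1 without Tet plus 18 or 22 h replicate 1, Tet plus 16 h replicate 2 or Tet minus 20 h replicate 2. MHC class I genes that rose went from 2 to 1 without any Tet minus replicate 1, Tet plus 22 h replicate 1 or Tet plus 16 h replicate 2. The 1 that fell was 0 without Tet minus 16, 20 or 22 h replicate 2 or Tet plus 20 h replicate 2. Genes of the BCL2 family that fell went from 2 to 1 without Tet plus 16 or 18 h replicate 1 or Tet minus 16 or 18 h replicate 2. Of the noradrenergic genes 1 fell without Tet minus 18 or 20 h replicate 1 or Tet plus 22 h replicate 2. Cytosolic ribosomal protein genes that rose went up without any of 5 libraries, to 3 without Tet plus 20 h replicate 1. MYCN neighbours that fell went down to 1 without Tet plus 20 h replicate 2. The 1 p53 target that fell was 0 or 2 without any of 10 of the 16 libraries.

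Among the 4814 genes meeting the naming rule at 16 to 22 h, the 5 largest increases were in small nucleolar RNAs, which guide modification of ribosomal RNA. SNORA2A rose by 4.65 (SE 0.385, adjusted p = 1.29e-10), SNORD15A by 4.33 (SE 0.401, adjusted p = 9.56e-10), SNORA50 by 3.82 (SE 0.367), SNORA71B by 3.45 (SE 0.334) and SNORA9 by 3.44 (SE 0.389). Of 208 small nucleolar RNAs tested, a group singled out after these values were seen, 107 rose and 15 fell (median 0.58), while at 0 to 14 h 2 rose and 71 fell (median -0.26; 4 and 83 with the block, and 1 to 6 rose without 1 library). Their summed share of counts, Cajal body RNAs included, was not lower in Tet plus at 0 to 14 h (median 0.476% against 0.446%), so the 71 do not stand for their summed level. In all 7713 genes differed at 16 to 22 h (3821 higher, 3892 lower), with 750 at least 2-fold higher, 81 of them small nucleolar RNAs, and 325 at least 2-fold lower. By time, 3918, 2721, 3477 and 4127 genes differed at 16, 18, 20 and 22 h, and 4353 and 5355 at 18 and 20 h with the replicate block. Without 1 of the 4 libraries of a time these 4 counts dropped as low as 2213, 1337, 1876 and 2237, the lowest at 18 h without Tet minus 18 h replicate 2.

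The arm difference at 16 to 22 h departed from that at 0 to 14 h for 2988 genes (1198 upward, 1790 downward; 4605 with the replicate block). MCM3 was lowered further by 0.89 on the log2 scale (difference -0.89, adjusted p = 2.54e-08) and TK1 by more (difference -1.29, adjusted p = 1.95e-09). MYCN itself did not show a detectable difference between the periods (0.015, SE 0.0762, adjusted p = 0.931). This comparison carries the run of the late Tet plus libraries.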

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

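Of the tests below, the 4 counts of other splits of the libraries were chosen before the data were examined; every other test of an explanation, and the comparison of the arms in their change from 16 to 22 h, was chosen after the result was seen, the one by share of counts after the one by step from 14 to 16 h was known.

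Of 208 small nucleolar RNAs 71 were lower and 2 higher in Tet plus cells at 0 to 14 h, where their share of counts was not lower (median 0.476% against 0.446%), and 15 were lower and 107 higher at 16 to 22 h; for 107 the 2 differences differed by the test of the difference itself. The other sequencing run is not excluded as the cause. RMRP, another non-coding RNA, took 1.56% to 2.5% of gene counts in the 8 Tet plus libraries at 16 to 22 h. In the other 36 it took at most 1.5%. RPPH1 took 1.19% to 2.01% in the 8 libraries and at most 1.37% in the others. The median step from 14 to 16 h in Tet plus cells was 0.521 (0.253 and 0.738 by replicate) and -0.146 in Tet minus (0.142 and -0.671), and the lowest share of counts in the 8 libraries was 0.935% against a highest of 0.806% in the other 36, but all 8 libraries of that run are Tet plus at 16 to 22 h, so run and shRNA cannot be told apart for these RNAs. A rise in the transcripts of the genes that hold them is argued against for the 85 of 107 risen RNAs with a host found. These rose by a median of 1.69, while their 67 host transcripts had a median of -0.19 (-0.139 and -0.157 by replicate), 3 higher and 28 lower. Transcription of the hosts was not measured, and transcript levels cannot decide whether it rose. For all 208 a rise in host transcripts was not decided (hosts -0.17, 6 of 92 higher and 39 lower), since a host was found for 75.5%. An effect of lowered MYCN stays open and untested.

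G1/S and G2/M genes were lower in Tet plus cells averaged over 16 to 22 h. For G2/M genes the median was 0.14 at 16 h, where 11 of 58 rose and 3 fell, and it was below 0 from 18 h. With an estimated correlation the set test did not pass at 16 h (camera adjusted p = 0.464) or 18 h (0.0618). The other run as the whole cause is argued against for G1/S genes by the median difference at 14 h, in shared lanes, of -0.839 (-0.852 and -0.804 by replicate), and for G2/M genes by the arm difference in the change from 16 to 22 h, each arm within its own run, of -1.44 (-1.45 and -1.43 by replicate). A lag of up to 4 h in Tet plus cells was not decided by the change from 16 to 22 h. G1/S genes changed by a median of -0.104 in Tet plus cells, but the replicates differed in sign (0.0277 and -0.28). Tet minus cells gained 0.397 and 0.399 from 12 to 18 h. The levels argue against such a lag as the whole cause for G1/S genes, though by a comparison across lanes. Their mean log2 CPM in Tet minus was lowest at 10 h (6.78 ± 0.0619, SD, n = 2). In Tet plus it was lower than that at 14 h (6.32 ± 0.18) and at 22 h (6.19 ± 0.0199). Neither of these times shares lanes with Tet minus at 10 h, and 22 h is from the other run. At 0 h the arms differed by -0.204 (Tet plus minus Tet minus). From 0 h the mean changed by -0.522 in Tet minus at 10 h and by -0.787 in Tet plus at 14 h. A longer lag and other effects of lowered MYCN stay open and were not tested.

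MYCN transcript was lowered by 17.3% at 0 to 14 h. Whether the scaling hid a larger decrease at 0 to 14 h was not decided. The lower of the values with DESeq2 size factors and with ERCC scaling was -0.27. DESeq2 size factors, like the TMM factors, take the bulk of genes as unchanged, so they cannot show a shift of all genes. ERCC scaling gave a smaller decrease, but ERCC shares in Tet plus libraries at 0 to 14 h ranged from 0.736% to 5.85%. The basis of the spike-in amount is not given. Loss of copies of the amplified region was not decided. Copies were not measured, and transcript levels of neighbours cannot tell them from regulation. The neighbour NBAS was not lower (0.169, SE 0.0664), although its call ended without any of 14 of the 28 libraries. DDX1, the other abundant neighbour, was lower (-0.10, SE 0.0394), so the 2 went opposite ways. Reads of the antisense gene within the MYCN count were not excluded: its own median level was 3.37% of that of MYCN, but the strand setting of the counting is not given, and antisense reads assigned to MYCN would not appear there. Whether the shRNA acted more on MYCN protein than on its transcript was not tested, since protein was not measured.

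Other splits of the same libraries were counted, 91 in each case, each parting every pair of libraries with the same number. For the arm difference at 0 to 14 h, 1 of 91 (the real one) gave as many genes (6019, highest other 724). At 16 to 22 h 1 of 91 did (7713, highest other 5076). The real grouping keeps each same-numbered series of an arm whole, while these splits mix the series of the 2 arms. Libraries of a series shared deviations across times (median r 0.592 in Tet minus and 0.564 in Tet plus). For both counts these splits therefore cannot exclude chance differences between whole series. For the difference between the periods 4 of 91 gave as many as 2988, under 0.05 of the splits. Another split gave 4907, so chance is not called excluded for this count. That split gave 4498 genes at 16 to 22 h and 0 at 0 to 14 h, and the reason was not tested. For the dependence on time 5 of 91 gave as many as 2, so chance cannot be excluded, and another split gave 1610. Among 8 splits free to keep pairs together the highest counts were 2390, 846, 1252 and 0. The split by replicate number, which keeps each series whole, gave 4045, 1287, 0 and 1.

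A difference between the arm effects at 16 to 22 h and at 0 to 14 h, by its own test, was found for 2988 genes, and the change from 16 to 22 h differed between arms for 1613. Among genes named here the later effect was higher by 0.357 in CADPS, 0.425 in CCNG2, 0.464 in MYCNOS, 0.504 in PAOX, 0.57 in BCL2, 0.623 in TP53INP1 and 0.849 in CDKN1C, and by 3.28 in SNORA50, 3.32 in SNORA71B, 3.46 in SNORA9, 4.01 in SNORD15A and 4.44 in SNORA2A. In cell cycle and histone genes the difference was -0.408 in CCNE2, -0.414 in NUF2, -0.434 in KIF14, -0.52 in AURKA, -0.604 in TOP2A, -0.733 in MCM10, -0.817 in ORC1, -0.871 in HIST1H2AB, -0.885 in PIF1, -0.893 in MCM3, -1.05 in HIST1H3D, -1.29 in TK1 and -1.87 in HIST1H2BF. In growth and metabolic genes it was -0.297 in DHX37, -0.30 in CD3EAP, -0.317 in IMPDH1, -0.343 in TRAP1, -0.357 in RRS1, -0.37 in MYBBP1A and -0.517 in LDHA. In transporters it was -0.529 in SLC7A5, -0.636 in SLCO4A1 and -1.04 in SLC29A1. In the small nucleolar RNA host SNHG1 it was -0.51. The arm effect depended on time within 0 to 14 h in 2 genes, ZNF367 (adjusted p = 0.0295) and HIST1H3D (adjusted p = 0.0425), calls that ended without any of 15 and 24 of the 28 libraries. Groups of 2 libraries were not tested for a library far from the other.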

How the results depend on the processing

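The count without small nucleolar RNAs was chosen after the data were seen; the other alternatives were fixed before. At 0 to 14 h the arm difference gave 4231 to 8077 genes under every alternative except ERCC scaling (48, 44 higher and 4 lower, against 2924 and 3095), and at 16 to 22 h 6183 to 9100 except ERCC scaling (14510 higher and 0 lower, against 3821 and 3892). The difference between the periods gave 14464, all upward, with ERCC scaling and 4605 with the replicate block. ERCC scaling moved the median of all genes from 0.00949 to 0.132 at 0 to 14 h and from 0.019 to 4.40 at 16 to 22 h, where ERCC transcripts per gene count were 18.7-fold higher in Tet minus; it gave 62 and 14530 genes over the Tet minus and Tet plus courses. It turned the sign of DDX1 at 0 to 14 h (0.015) and, at 16 to 22 h, of HIST1H2BF (2.44), MCM3 (2.36), MYCN (4.12), SLC29A1 (2.58), SLCO4A1 (2.6) and TK1 (2.56). Of 160 called pairs of named gene and comparison, 132 lost the call under at least 1 alternative and 128 under ERCC scaling. The cause was not tested: the amount of spike-in added may differ between libraries. Without small nucleolar RNAs 7580 genes differed at 16 to 22 h and 2855 between the periods.

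The replicate block, which takes out what same-numbered libraries share, gave 1174, 1301, 2525, 1800, 1504, 1846 and 2353 genes at 0, 3, 6, 8, 10, 12 and 14 h, and 4353 and 5355 at 18 and 20 h. Within an arm it gave 6805 and 9241 genes over the Tet minus and Tet plus courses, 917 and 1248 for 6 against 0 h, 280 and 118 for 12 against 8 h and 1785 and 2653 for 22 against 16 h. Same-numbered libraries of an arm shared deviations at 54 of 55 and 53 of 55 pairs of times (median r 0.592 and 0.564, lowest 0.0647 and -0.0679). Libraries with the same number are therefore not independent across times, although the main fit, which has no block, takes them as independent. DESeq2 gave 406 for 22 against 16 h in Tet minus and 52 for 12 against 8 h in Tet plus. The Tet minus libraries alone gave 1326 over their course, and the Tet plus course over 0 to 14 h alone 1510, with fewer libraries. Dependence on time gave 954 genes over all 11 times, 33 by DESeq2, 22 with the block and 6 without a filter. It gave 0 with ERCC scaling and 0 from the 28 libraries at 0 to 14 h alone. From all libraries edgeR had 265 of 14534 genes at an unadjusted p under 0.05, a smaller share than 0.05. The cause was not tested.

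Leaving out 1 library, with the lone library of its group assumed to vary like the others, gave 5605 to 6001 genes at 0 to 14 h, 7155 to 7519 at 16 to 22 h, 2603 to 3229 for the difference between the periods and 4971 to 5736 over the Tet plus course. The Tet minus course ranged from 1711 (without Tet minus 3 h replicate 2) to 3283, and dependence on time from 0 to 5, moved over 1.5-fold by 25 of 28 libraries; the highest count came without Tet plus 6 h replicate 1. Of 50 set tests, 22 lost the call with an estimated correlation, which was most of those that had passed. The calls that held were ribosome biogenesis and nucleotide synthesis in both periods and G1/S genes at 16 to 22 h. With the block 3 set tests gained the call. The block ended no call of a set test or named gene and changed no set call other than these 3; 13 pairs of named gene and comparison gained a call, and the list counts that it moved over 1.5-fold stand beside the lists. With fry 12 gained the call and 38 did not change: the MYC network, the BCL2 family, MHC class I genes and abundant non-coding RNAs in both periods, polyamine synthesis, ATF4 targets and G1 cyclins at 0 to 14 h and cholesterol synthesis at 16 to 22 h.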

Other observations

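The comparison of the arms in their change from 16 to 22 h, used here, was chosen after the data were seen, as were the genes named from it. Between 16 and 22 h G2/M genes moved apart in the 2 arms, each followed within its own sequencing run: the median log2 change was 0.839 in Tet minus and -0.584 in Tet plus cells, and 51 of 58 were lower in the difference (set adjusted p = 2.88e-79, and adjusted p = 0.000153 with an estimated correlation). TOP2A, which untangles DNA before mitosis, had a difference of -2.10, the kinetochore gene NUF2 one of -2.35 and the cytokinesis kinesin KIF14 one of -1.98 (adjusted p = 2.62e-07 for each, edgeR's quasi-likelihood test). Histone genes moved the other way, with 16 of 35 higher in the difference (median 1.02, set adjusted p = 3.30e-12, and adjusted p = 0.552 with an estimated correlation). In all 1613 genes differed (514 upward, 1099 downward), and 3979 with the replicate block.

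Of the genes next to MYCN, DDX1 and NBAS were among the most abundant transcripts and others were not. DDX1 had a median of 10320 CPM over the 44 libraries (rank 3) and NBAS one of 8050 CPM (rank 5), against 1091 CPM for MYCN (rank 61, range 870.6 to 1479 CPM) and 38.39 CPM for MYCNOS. FAM49A, on the other side of MYCN, was at 4.783 CPM and was higher in Tet plus cells at 0 to 14 h (log2 fold change 0.74, SE 0.0935, adjusted p = 4.24e-07).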
